A study of Bos indicus with 6 samples.

How the data were processed

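Endometrial RNA was sequenced from 6 Nelore cows, a Bos indicus beef breed, with 3 cows in each of 2 hormonal regimens. The LF-LCL regimen (large follicle, large corpus luteum) included the prostaglandin analogue cloprostenol on day -10, and the SF-SCL regimen (small follicle, small corpus luteum) did not. The corpus luteum (CL) is the gland that forms from the ovulated follicle and secretes progesterone. The interval from withdrawal of the progesterone-releasing device to GnRH on day 0 was 42 to 54 hours in LF-LCL and 30 to 36 hours in SF-SCL, per the labels' protocols. Tissue was taken at slaughter on day 7. The labels' protocols place 35 cows in the LF-LCL arm and 39 in the SF-SCL arm of the trial of 74 animals, and how the 6 sequenced cows were chosen is not given in the sources used here.

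The deposited values are a non-negative signal per gene, namely read counts divided by a size factor for each library, in 1 table with 24616 Ensembl cattle gene identifiers and 1 column per cow. CASAVA 1.8.2, Bowtie2 2.1.0, SAMtools 0.1.18, HTSeq 0.5.4p2 and DESeq 1.12.1 are named in the submitters' processing notes, without roles or order. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. That the values are scaled counts was read from the values themselves. In each column every value above 0 was a whole multiple of the smallest one, to within 0.01 reads, for 100% of values. The implied size factors equalled the median-of-ratios factors recomputed from the recovered reads to all 5 digits kept (0.64689 for SF-SCL replicate 3 up to 1.7787 for LF-LCL replicate 1). Size factors make libraries comparable on the assumption that most genes did not change. Whole reads could therefore be recovered for count-based tests.

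Recovered totals ranged from 2896663 to 7811332 reads. One read corresponded to a normalised read count of 0.56222 in the deepest library and 1.5458 in the shallowest. A count of 0 allows up to 3 reads, a normalised read count of 1.69 in the deepest and 4.64 in the shallowest library. This limit covers counting error only, since reads without molecular identifiers are not independent molecules.

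The main test was chosen for normalised values. Genes with a mean of at least 1 over the 6 libraries were tested with limma (version 3.58.1, R 4.3.3) on log2(value + 1) with a mean-variance trend, group as the only term, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, two-sided, and is termed higher or lower in LF-LCL relative to SF-SCL. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. edgeR (4.0.16, quasi-likelihood test) was run on the recovered reads as an alternative added after the file was seen, as was limma on values rescaled by TMM. The other alternatives were pseudocounts of 0.1 and 5, no filter on low values, an adjusted p under 0.1, other edgeR scalings and filters (RLE, upper quartile, no filter, 1 CPM in every library of a group), a robust spread estimate, DESeq2 (1.42.0), limma-voom with and without library weights, and leaving out each library in turn. The design, these alternatives and the rule for naming genes were set before the data were examined. The design had assumed deposited counts, for which this edgeR test was to be the main one. It gave limma as the test for normalised values, so the main result here comes from that fallback.

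Replicate numbers follow accession order and pair no cows. Library pairs were compared by chi-square per degree of freedom to look for 1 library deposited under 2 names. The labels describe separate cows, and no sequencing batch, lane or date is given in the sources used here, so no within-batch value could be computed. The position of each library between the groups was computed on the 200 genes with the smallest p in a fit without that library, by least-squares projection of its log2 values between the SF-SCL mean (0) and the LF-LCL mean (1) of the remaining libraries. Principal components and within-group spreads used the 9517 genes with a mean log2 value above 4.

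The file does not pair its identifiers with gene names. The gene table used here holds no Ensembl identifiers, so 0 of 24616 identifiers matched it. The 34 gene lists drawn up beforehand (844 genes of progesterone and estradiol response, matrix, transport, cell cycle and cell types) were therefore not tested, and gene functions, coordinates and reads shared between near-identical copies or overlapping genes were not analysed here. The naming rule took called genes with groups that did not overlap, in order of absolute log2 fold change. It required a gene symbol, so it was applied to identifiers instead and limited to 2 genes per direction. Its other parts, on list members and fixed symbols, could not be applied.

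The tests were tested on simulated data. Counts were drawn for the real genes, means, spreads and depths of this comparison, with 200 genes changed, 50 at each fold. Of 12528 simulated genes tested by limma, calls were made on 2% of those changed by 1.5-fold, 38% at 2-fold, 64% at 4-fold and 84% at 8-fold, and 7 of the 101 calls fell on unchanged genes. Simulated genes varied independently of each other, so these shares hold for that setting and for the folds chosen.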

Results

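Endometrial transcriptomes were compared on day 7 after GnRH between cows managed to ovulate a large follicle and carry a large CL (LF-LCL, 3 cows) and cows managed to ovulate a small follicle and carry a small CL (SF-SCL, 3 cows). The endometrium is the uterine lining that the early embryo meets, and its gene expression responds to estradiol from the follicle and to progesterone from the CL. The comparison asks whether the hormonal regimen around ovulation was accompanied by a different endometrial transcriptome. The LF-LCL libraries held 7811332, 5844269 and 3219678 reads assigned to genes in replicates 1 to 3, and the SF-SCL libraries 3363191, 5992987 and 2896663. Of 24616 genes, 15468 had at least 1 read in some library and 9148 had none in any. The most abundant gene took 1.26% to 1.98% of a library's normalised reads, and the 100 most abundant took 17.4% to 20.4%. Library pairs differed by at least 9.19 times the sampling variance (chi-square per degree of freedom), so none was treated as a repeat of another.

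A limited set of genes was called between the groups, and more of the called genes were higher than lower in LF-LCL. Of 12535 genes tested, 121 (0.965%) were called, 84 higher and 37 lower in LF-LCL (limma, adjusted p under 0.05, 3 cows per group). The genes that were higher had a median fold of 2.26 (quartiles 1.83 and 3.44), and those that were lower a median fold of 2.56 (quartiles 2.14 and 4.23). Changes of at least 2-fold were seen for 54 of the higher and 30 of the lower genes, and changes of at least 4-fold for 16 and 10. The groups did not overlap for 22.8% of all tested genes, a property that chance gives to 10%. A further 1013 genes had a fitted difference of at least 2-fold without passing the threshold. Splits of the same cows into 3 and 3 that mixed the regimens gave 575 to 857 genes at 2-fold or more, against 1097 here. The lower tertile by abundance held 754 of these 1097, and its median standard error of a log2 fold change was 0.568. The 1013 therefore cannot be read as further genes that differed between the regimens. Over all tested genes, called or not, the fitted 2-fold differences between the regimens ran the other way from the calls. In LF-LCL, 440 genes were at least 2-fold higher and 657 at least 2-fold lower. This surplus of lower genes lay mainly in the lower tertile by abundance (254 higher and 500 lower). The middle tertile held 99 higher and 120 lower, and the upper tertile ran the same way as the calls (87 higher and 37 lower). The number of calls does not measure how many genes differed, and neither does the count of 2143 genes (17.1%) with an unadjusted limma p under 0.05. Where no gene differs, a share of 0.05 is expected to pass that threshold. The other splits, which mixed the regimens, gave 278 to 943 such genes. In simulated data, where genes varied independently of each other, limma called 38% of genes changed by 2-fold.

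The called genes were mainly abundant ones. With the tested genes divided into tertiles of equal size by abundance, the upper tertile by mean normalised read count (250 and above) held 83 calls, 65 higher and 18 lower in LF-LCL. The middle tertile held 31 calls, 17 higher and 14 lower, and the lower tertile (below 38) held 7, of which 2 were higher and 5 lower. The median standard error of a log2 fold change was 0.138 in the upper tertile and 0.568 in the lower tertile. Among the 100 most abundant genes 5 were called, and all 5 were higher in LF-LCL. The 84 higher genes together took 2.92% ± 0.14 (SD, n = 3) of normalised reads in LF-LCL and 1.23% ± 0.12 (SD, n = 3) in SF-SCL. The 37 lower genes took 0.223% ± 0.0087 (SD, n = 3) and 0.498% ± 0.048 (SD, n = 3). These shares describe genes selected for their difference and are not a separate test.

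**Figure D1:**
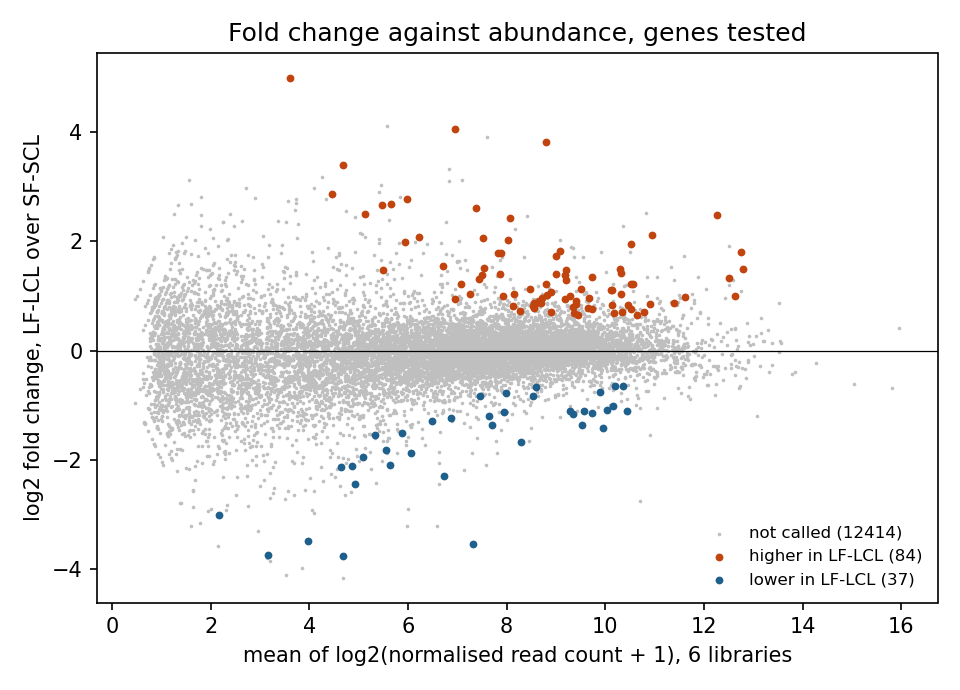
Each point is 1 of the 12535 tested genes, with the mean of log2(normalised read count + 1) over the 6 libraries on the horizontal axis and the log2 fold change of LF-LCL over SF-SCL on the vertical axis. The 84 genes called higher (orange) include most of the abundant called genes, and the 37 called lower are in blue.

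The highest-ranked gene among those higher in LF-LCL, ENSBTAG00000037786, was near the detection limit in SF-SCL. Its normalised read count was 69.54 ± 20.1 (SD, n = 3) in LF-LCL and 3.035 ± 5.26 (SD, n = 3) in SF-SCL, where 2 of the 3 libraries had no read. The SF-SCL group held 7 reads of this gene in all, against 249 in LF-LCL. The log2 fold change was 4.99 with a standard error of 0.865 (limma, adjusted p = 0.048), and edgeR on the recovered reads did not call it (adjusted p = 0.0597). The size of this fold rested on the low SF-SCL values. The log2 fold change was 3.37 with a pseudocount of 5 and 7.23 with a pseudocount of 0.1. It was 6.10 without SF-SCL replicate 1, where both remaining SF-SCL libraries were at 0 and the fitted value depends on the pseudocount. The gene stayed called without SF-SCL replicate 1 or 3 (limma, adjusted p = 0.0153 and 0.0474), but not without any one of the other libraries (limma, adjusted p = 0.106 to 0.156). It was also not called with a pseudocount of 0.1 (limma, adjusted p = 0.0839) or with DESeq2 (adjusted p = 0.0773). The gene ranked next, ENSBTAG00000013550, had the larger log2 fold change of these 2 genes with a pseudocount of 5 (3.85 against 3.37) and without SF-SCL replicate 3 (4.82 against 4.43). Its normalised read count was 522.8 ± 172 (SD, n = 3) in LF-LCL and 39.95 ± 39.3 (SD, n = 3) in SF-SCL. Its log2 fold change was 4.06 with a standard error of 0.599 (limma, adjusted p = 0.0417; edgeR, adjusted p = 0.0445). Within SF-SCL it was at 13.01 and 21.82 in replicates 1 and 2 and at 85.02 in replicate 3, and the log2 fold change was 4.82 without replicate 3 (limma, adjusted p = 0.00239). Without any one of the other 5 libraries the gene was not called (log2 fold change 3.51 to 4.34; limma, adjusted p = 0.0817 to 0.13), nor was it with upper quartile scaling (edgeR, adjusted p = 0.0503).

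Among the genes lower in LF-LCL, ENSBTAG00000047594 and ENSBTAG00000047087 ranked first. ENSBTAG00000047594 had a normalised read count of 7.207 ± 5.66 (SD, n = 3) in LF-LCL and 96.13 ± 27.3 (SD, n = 3) in SF-SCL, a log2 fold change of -3.76 with a standard error of 0.529 (limma, adjusted p = 0.0379; edgeR, adjusted p = 0.0445). It was -3.11 with a pseudocount of 5, and the gene was not called without any one of the libraries other than SF-SCL replicate 3 (limma, adjusted p = 0.0711 to 0.132). ENSBTAG00000047087 was at 2.054 ± 2.27 (SD, n = 3) in LF-LCL, from 10 reads in all, and at 32.41 ± 9.3 (SD, n = 3) in SF-SCL, from 91 reads. Its log2 fold change was -3.73 with a standard error of 0.65 (limma, adjusted p = 0.048), and edgeR did not call it (adjusted p = 0.0526). This log2 fold change was -2.42 with a pseudocount of 5, -5.08 with a pseudocount of 0.1, -4.31 without LF-LCL replicate 1 and -3.08 without LF-LCL replicate 3. ENSBTAG00000047087 was not called without any one of the 6 libraries (limma, adjusted p = 0.058 to 0.159), nor with a pseudocount of 0.1 (limma, adjusted p = 0.11). The names and functions of these 4 genes were not analysed here.

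**Figure D2:**
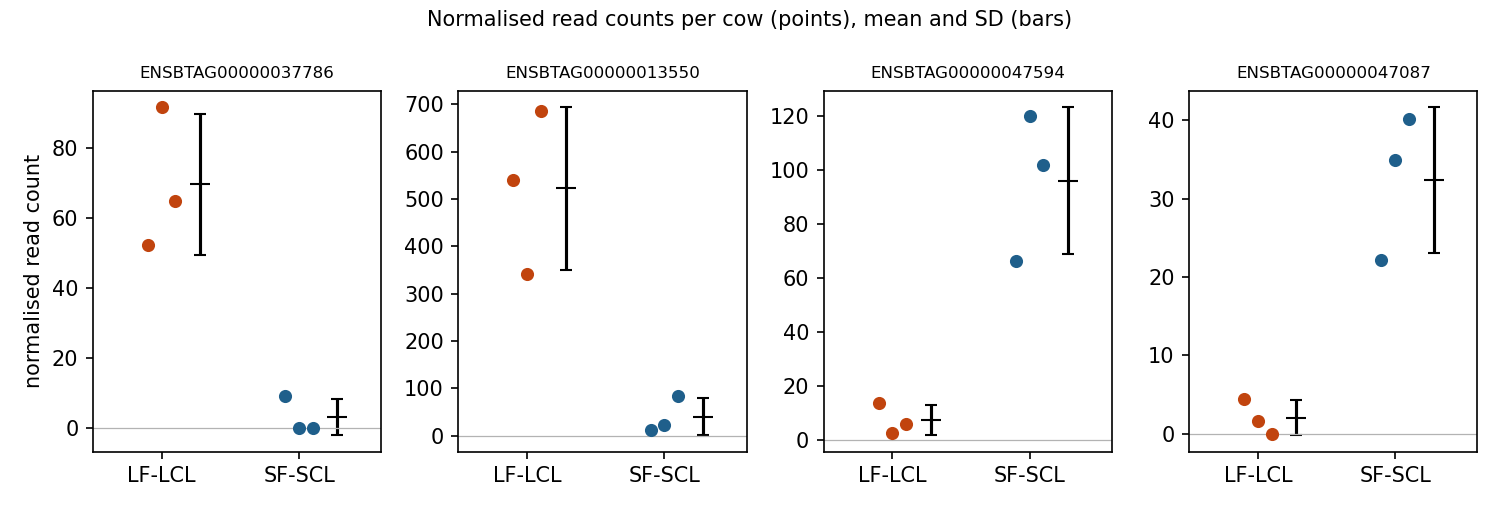
Normalised read counts of the 4 named genes in each cow (points, replicates 1 to 3 from left to right), with the group mean and SD beside them; each panel has its own linear vertical axis. The groups are separated in every panel because the naming rule required it. The lowest values lie at 0 in SF-SCL for ENSBTAG00000037786 and in LF-LCL for ENSBTAG00000047087.

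The main axis of variation among the 6 libraries separated the regimens, and SF-SCL replicate 3 lay nearest to the other group. The first principal component held 40.1% of the variance over 9517 genes, with LF-LCL scores of 19.1, 28.1 and 23.6. The SF-SCL scores were -29.3, -33.7 and -7.89. The groups did not overlap on this component, which with 3 against 3 gives an exact permutation p of 0.1, the smallest this design allows. The root mean square log2 difference between 2 cows was 0.539 to 0.631 within LF-LCL, 0.433 to 0.603 within SF-SCL and 0.575 to 0.744 between the groups, so single pairs from different groups were at times closer than pairs from the same group. The biological coefficient of variation was 22.3% within LF-LCL and 20.6% within SF-SCL.

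**Figure D3:**
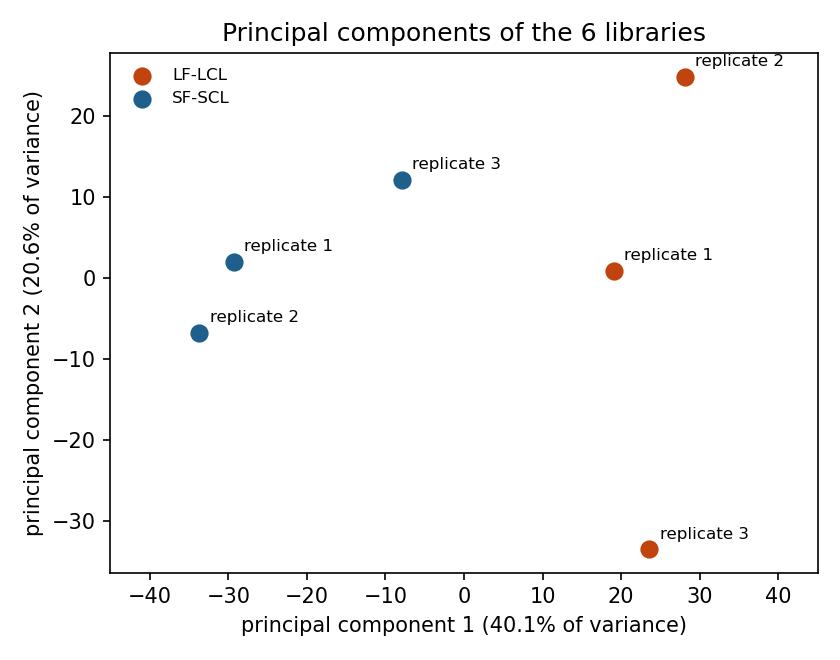
Scores of the 6 libraries on the first (40.1% of variance, horizontal) and second (20.6%, vertical) principal components of log2 normalised read counts. The LF-LCL cows lie between 19.1 and 28.1 on the first component, and SF-SCL replicate 3 lies at -7.89, apart from the other SF-SCL cows.

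On the 200 genes that best separated the groups when a library was left out, the left-out LF-LCL libraries lay at 0.71, 0.715 and 0.641 of the way from the SF-SCL mean to the LF-LCL mean. The left-out SF-SCL replicates 1 and 2 lay at 0.201 and 0.0177, and replicate 3 lay at 0.529. In simulated data where all cows of a group shared the same effect, the SF-SCL libraries lay at 0.202 to 0.22 and the LF-LCL libraries at 0.784 to 0.843. With SF-SCL replicate 3 simulated midway between the groups, it lay at 0.495. The simulated genes varied independently of each other, with 200 changed by 1.5-fold to 8-fold. These positions are therefore no direct reference for the real libraries.

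**Figure D4:**
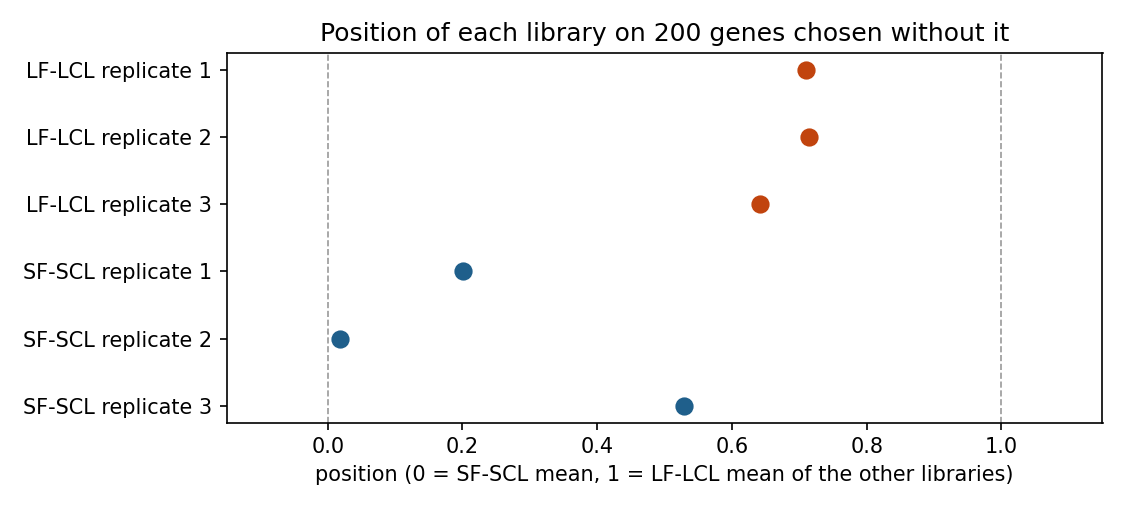
Position of each library on the 200 genes with the smallest p in a fit without it, where 0 is the mean of the remaining SF-SCL libraries and 1 that of the remaining LF-LCL libraries (dashed lines). SF-SCL replicate 3, at 0.529, lies between the other SF-SCL cows and the LF-LCL cows.

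The number of called genes varied when a cow was left out and between tests. With limma, 370 genes were called without SF-SCL replicate 3, whereas 1, 0 and 12 were called without LF-LCL replicates 1, 2 and 3 and 2 and 0 without SF-SCL replicates 1 and 2. Each of these fits compared 3 cows with 2, so a lower count does not by itself point to the cow left out. All 121 genes kept their direction and an unadjusted p under 0.05 in each of these 6 fits, although they had been selected on the same cows. edgeR called 85 genes, 61 higher and 24 lower, and all 85 were among the 121, while DESeq2 called 685. With upper quartile scaling edgeR called 31 genes higher and 24 lower, so the excess of higher genes was smaller under that scaling. Across all 14 tests and settings that used the 6 cows at an adjusted p under 0.05, 52 genes were called every time, 31 higher and 21 lower.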

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

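Limma called 121 genes. The count changed by more than 1.5 times with DESeq2 (685), limma-voom with library weights (412), edgeR without a filter (391), edgeR with upper quartile factors (55) and an adjusted p under 0.1 (500); the cause was not tested. Leaving out 1 library gave 0 to 370 calls: 370 without SF-SCL replicate 3, 2 and 0 without SF-SCL replicates 1 and 2, and 1, 0 and 12 without LF-LCL replicates 1, 2 and 3. In the limma fits with 0 calls, 1865 genes (without LF-LCL replicate 2) and 1580 genes (without SF-SCL replicate 2) had an unadjusted p under 0.05, and edgeR also called 0. The remaining 9 alternatives with all 6 libraries called 81 to 143 genes. More genes were higher than lower in LF-LCL under every setting that called any, from 56.4% with upper quartile factors to 100% in the fits with 1 or 2 calls. The 4 named genes kept their direction in all 76 values under alternatives. They missed the threshold in 13 of 52 values with all libraries and in 20 of 24 with 1 library left out, and adjusted p ranged from 1.11e-08 to 0.159. The planned tests of gene lists, list members and genes chosen by symbol were not run, because the gene table used here could not pair the identifiers with names. After thinning all libraries to 2896663 reads limma called a median of 119 genes (75 to 143 in 20 thinnings). The median standard error was largest in the lower tertile of genes by abundance (0.568), where counting noise and spread between cows were not separated. In simulated data of this comparison, where genes varied independently of each other, limma called 38% of genes changed by 2-fold.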

Other observations

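The tests of splits, depth, mixing and labels were specified before their results were seen. The bootstrap interval of the position, used for labels, was not part of the rule written beforehand. Chosen after the data had been examined were the test of scaling, the other SF-SCL libraries as a reference for mixing and the gene sets of 50 and 1000. The counts of rare and abundant genes and the position of SF-SCL replicate 3 as a pattern to follow were also chosen then.

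Differences of at least 2-fold were mostly towards higher values in LF-LCL among abundant genes and mostly towards lower values among rare ones. In the upper tertile of genes by abundance, 87 were at least 2-fold higher in LF-LCL and 37 at least 2-fold lower, whether called or not. In the middle tertile the counts were 99 and 120, and in the lower tertile 254 and 500, which gives 440 and 657 over all tested genes. Without SF-SCL replicate 3 the upper tertile held 138 higher and 54 lower genes. The surplus of lower genes among rare ones shrank to 364 against 482 without LF-LCL replicate 2, and the counts were 288 against 716 without LF-LCL replicate 1. Another split of the same cows, LF-LCL replicate 1 with SF-SCL replicates 1 and 2 against the rest, gave an imbalance of 512 against 167. At an equal 2896663 reads per library, LF-LCL replicate 2 had the fewest genes with a read (12159.2, mean of 20 random thinnings), and the other libraries had 12566 to 12798.7. The group means were 12491.2 ± 300 (SD, n = 3) in LF-LCL and 12707.1 ± 124 (SD, n = 3) in SF-SCL (exact permutation test, two-sided, p = 0.3, where the smallest possible is 0.1). Only 3 genes were all-or-none, with at least 3 reads in every cow of one group and none in the other, 1 in LF-LCL and 2 in SF-SCL.

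The 121 calls were set against other groupings of the same cows. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls, the real one, and the highest of the other splits gave 1 call. With 10 splits the share cannot fall under 0.05. Unequal depth is argued against as the cause by thinning. After thinning every library to 2896663 reads edgeR called a median of 91.5 genes (60 to 135 in 20 thinnings) against 85 without thinning. The split of the 3 deepest libraries from the 3 shallowest gave 0 calls with limma and 0 with edgeR (311 genes at an unadjusted limma p under 0.05). That split could not decide, because every split that mixed the regimens gave at most 1 call. A sequencing or handling batch that follows the regimen stays open, since no batch is given in the sources used here.

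SF-SCL replicate 3 may have had an endometrial profile intermediate between the regimens, with a held-out position of 0.529 (0.517 on 50 genes, 0.47 on 1000). Its low depth is argued against, because at equal depth it still lay at least 0.278 above the next SF-SCL library in each of 20 thinnings. LF-LCL RNA mixed into the library stays open. The median linear mixing fraction was 0.37 on genes higher in LF-LCL (95% bootstrap interval 0.327 to 0.404) and 0.608 on genes lower (0.546 to 0.785). A shared fraction would not give this, and the rule written beforehand counted intervals that do not overlap against mixing. However, the other SF-SCL libraries showed gaps of the same size (0.261 and 0.362, against 0.238 here), so the test cannot decide. The cause of these gaps was not tested. A wrong label also stays open. The library lay 0.112 below the lowest LF-LCL position, beyond the LF-LCL range of 0.074, which the rule written beforehand counted against a wrong label. It lay 0.182 below on 1000 genes (range 0.08), but 0.023 below on 50 genes (range 0.149). The bootstrap interval of the position over genes (0.465 to 0.589) stays below the lowest LF-LCL library (0.641), though not by more than the LF-LCL range. A range over 3 cows is a weak bound for a further cow. Each position also has its own genes and reference means, and the SF-SCL mean used for the LF-LCL libraries includes replicate 3. The gap therefore compares unlike scales and cannot decide. A cow whose own follicle or CL response was intermediate is the hypothesis the regimen offers, and it was not tested here, as hormone or follicle values per cow were not used.

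The excess of higher genes among the calls (69.4%) could depend in part on how libraries were scaled, and on the test and threshold used. It was 72.2% with limma and 71.8% with edgeR under TMM scaling, but 56.4% with edgeR under upper quartile factors, which moved the median log2 fold change of all genes to -0.079. The share stayed above 50% but fell below 60%, the bound against a scaling cause. That bound was set after the TMM result and before the upper quartile result was seen. Without a change of scaling method the share was 59.9% with DESeq2 and 63% with limma at an adjusted p under 0.1. Among all tested genes whose groups did not overlap, 1478 were higher and 1376 lower in LF-LCL. Scaling, the test and threshold, and an excess in the tissue therefore cannot be told apart for these calls.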
